A study of Mus musculus with 6 samples.

How the data were processed

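Poly(A)-selected RNA of mouse embryonic hearts was sequenced from 6 libraries, in 3 groups of 2. The labels name a control group, a group with heterozygous and a group with homozygous deletion of the gene for the splicing regulator Rbfox2. Deletion came from crossing mice with a floxed Rbfox2 allele to mice that express Cre recombinase from Nkx2-5, a gene of early heart progenitors. Group and replicate number of each library were taken from the sample titles. Embryonic stage, the genotype of the controls, and whether the control embryos carried the Cre allele, are not given in the sources used here.

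Per the labels' protocols, total RNA was extracted with Trizol, 1 µg was used for strand-specific TruSeq libraries, and paired reads of 75 bases were sequenced on an Illumina NextSeq instrument. Per the submitters' processing notes, bcl2fastq 2.20 and STAR 2.5.4 were used with the GRCm38 mouse genome; the program that counted reads, its strand setting and its treatment of reads with several matches are not given in the sources used here. The authors deposited 1 table of raw counts of reads per gene, with 53379 Ensembl genes in rows and 6 columns that carry the sample titles. All values were whole numbers. Exon or junction counts were not analysed here, so nothing below measures splicing. A gene name table and the GRCm38 gene annotation gave a symbol and a position to 53274 of the 53379 identifiers.

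Total counts per library were 57066125 and 68825153 in the controls, 77372459 and 74154454 in the heterozygous group and 78582987 and 49980086 in the homozygous group. Genes were kept with the default filter of edgeR (filterByExpr, minimum count 10), which left 21356 genes and 99.9% of the counts. Library sizes were scaled by TMM. All 6 libraries entered one edgeR quasi-likelihood fit (robust glmQLFit, glmQLFTest) with genotype as the only term, so that the 3 groups shared 1 estimate of the spread, and 3 contrasts were tested with Benjamini-Hochberg adjustment and a threshold of 0.05. The common biological coefficient of variation was 0.245, with 3 residual degrees of freedom and a median of 4.74 prior degrees of freedom. Levels are in CPM, the usual unit of counts scaled to library size, with TMM factors, given as mean ± SD over 2 libraries, and fold changes are on the log2 scale with the standard error implied by the quasi-likelihood F statistic. The titles carry a code of their own for each library, and the 2 libraries of each group differed in Xist and Y-linked expression, so they do not come from the same embryo. The labels do not say whether a library holds 1 embryo or a pool, and p-values measure the spread between these libraries. No pair of libraries agreed within sampling noise.

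The tests, the alternatives, the rule for naming genes and 30 gene lists with 687 entries were fixed before the data were examined. The lists cover cardiomyocytes, other heart cells, signalling, metabolism, stress and tissues next to the heart; 686 entries matched a gene. Each list was tested per contrast with camera (limma) on log2 CPM with a preset correlation between genes of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 30 lists, and again with an estimated correlation and with fry. Named were Rbfox2; the called genes with a mean of at least 5 CPM, a symbol other than a predicted gene and no overlap between the groups, up to 12 per direction; in a comparison with under 5 calls, the 3 genes with the smallest p in each direction; and up to 4 members per list with the smallest p. Gm9825 and Gal in the homozygous comparison and Kif12, Gm9825, Foxa3 and Onecut3 in the heterozygous comparison were called but fell outside that rule, and were named after their values were seen. Some genes are not reported here. Every gene outside the lists that is named for a neighbouring tissue or for sterol synthesis was likewise named after its values were seen.

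The scripts were tested on simulated counts for the homozygous against control comparison, with 200 of 21356 genes changed in each of 5 simulations. Changed genes were drawn from those with a mean of at least 5 CPM. Counts were drawn with a spread set by the trend over mean level, so single genes did not vary around that trend. These rates may therefore not hold for the measured libraries. Recovery was 23.3% of genes changed 1.5-fold, 72.5% of those changed 2-fold and 98.5% of those changed 4-fold, and 25 of 693 calls were false. In the heterozygous against control comparison of the same simulations, where no gene was changed, 0 genes were called. The simulations of unchanged groups used for the genotype series drew a spread per gene, and calls did occur in them. Alternatives were RLE and upper-quartile scaling, no filter, a stricter filter (at least 1 CPM in at least 4 libraries), DESeq2, limma-voom, a fit on only the 2 groups compared, the replicate number as a block, removal of haemoglobin and mitochondrial genes, and leaving out each library in turn, where the lone library was assumed to vary like the other groups. A crossed replicate block, and a split with 1 control library for each comparison, were added after the data were seen. Sequences of 5 gene copies were compared with protein-coding transcripts by blastn. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and BLAST 2.17.0.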

Results

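Gene expression was measured by RNA sequencing in embryonic mouse hearts of a control group and of groups with 1 or 2 deleted alleles of Rbfox2, which encodes an RNA-binding protein that regulates alternative splicing. Each of the 3 groups (control, heterozygous deletion, homozygous deletion) held 2 libraries, with total counts between 49980086 and 78582987. The study asked how deletion in the early cardiovascular lineage alters splicing and expression; only expression per gene could be compared here. The libraries differed in more than genotype. Xist, the transcript of the inactive X chromosome, stood at 524 to 746 CPM in replicate 1 of every group and at 0.859 to 1.41 CPM in replicate 2, whereas the Y-linked gene Ddx3y stood at 59.7 to 77.5 CPM in replicate 2 and at 0 to 0.174 CPM in replicate 1. Each group thus held 1 Xist-high and 1 Y-expressing library. Counts above 0 were found for 37521 genes in control replicate 2, against 27976 to 31553 genes in the other 5 libraries. Homozygous replicate 1 was the only library with genes at 10 CPM or more and at least 10 times the highest level of the other 5. It had 24 such genes, which summed to 1872 CPM there and to at most 46.3 CPM in any other library. They included Prl8a2, a prolactin-family gene of the decidua, at 396 CPM against 0.784 to 2.07 CPM, and Erv3 at 419 CPM against 0.295 to 1.14 CPM.

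Rbfox2 stood lower in each deletion library than in either control. Rbfox2 (ENSMUSG00000033565; GRCm38 chromosome 15, 77078990 to 77307004, minus strand) stood at 333 ± 11.9 CPM in control, 235 ± 1.52 CPM in heterozygous and 119 ± 4.84 CPM in homozygous hearts (SD, n = 2 each). It fell in homozygous against control hearts, with a log2 fold change of −1.48 (SE 0.0909, edgeR quasi-likelihood adjusted p = 0.00151). The log2 fold change of heterozygous against control hearts was −0.50 (SE 0.0891, adjusted p = 0.242), and that of homozygous against heterozygous hearts was −0.98 (SE 0.0899, adjusted p = 0.0605). Neither passed over all genes, although in each comparison both libraries of one group lay below both of the other. Counts cover the whole gene, so transcripts that lack only the deleted exons would still be counted.

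**Figure D1:**
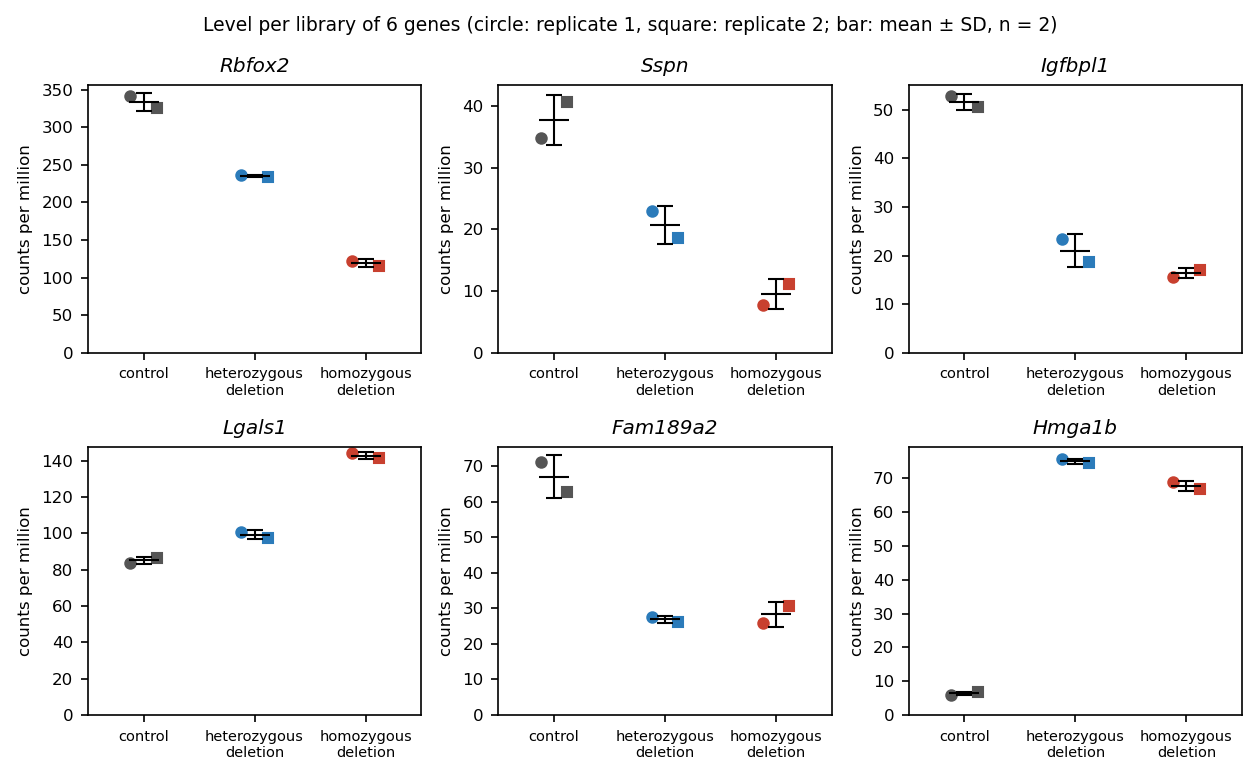
CPM (linear axis from 0) of 6 genes in each library, by group; circles are replicate 1, squares replicate 2, and bars the mean ± SD of 2 libraries. Rbfox2 and Sspn lay lowest in homozygous hearts, at 119 and 9.51 CPM, with heterozygous hearts between, whereas Fam189a2 and Hmga1b stood at nearly one level in both deletion groups, 26.9 and 28.3 CPM for Fam189a2.

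Homozygous deletion was compared with control to ask what the loss of both alleles changes. Beside Rbfox2, the genes that fell were Sspn, which encodes sarcospan of the dystrophin-associated complex, from 37.7 ± 4.02 to 9.51 ± 2.42 CPM (SD, n = 2 each, as for all levels); Igfbpl1, an insulin-like growth factor binding protein-like gene, from 51.7 ± 1.63 to 16.4 ± 1.04 CPM; Fam189a2, from 67.0 ± 6.07 to 28.3 ± 3.42 CPM; and Gal, the gene of the neuropeptide galanin, from 4.88 ± 0.0686 to 0.948 ± 0.0992 CPM. Lgals1, which encodes galectin-1, rose from 85.1 ± 1.70 to 142.7 ± 1.90 CPM. The largest rises were in 3 near-identical copies of other genes, Hmga1b (6.36 ± 0.454 to 67.8 ± 1.43 CPM), Gm9825 (1.17 ± 0.0897 to 20.2 ± 1.29 CPM) and Atp6v0c-ps2 (0.507 ± 0.0771 to 16.5 ± 0.569 CPM). Their counts are uncertain because they match Hmga1, Rnps1 and Atp6v0c at 99.8%, 99.4% and 99.8% identity.

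Sspn (ENSMUSG00000030255) lies on chromosome 6 (145931641 to 145965223), Igfbpl1 (ENSMUSG00000035551) on chromosome 4 (45809468 to 45826923) and Fam189a2 (ENSMUSG00000071604) on chromosome 19 (23972750 to 24031019). Lgals1 (ENSMUSG00000068220) lies on chromosome 15 (78926725 to 78930465), and Hmga1b (ENSMUSG00000078249) on chromosome 11 (120762794 to 120764419). Chromosome 15 also holds Rbfox2 (77078990 to 77307004), so Lgals1 lies within 10 Mb of the floxed locus. For Lgals1, linkage to that allele was not told apart from the loss of Rbfox2. In all, 4 genes rose and 5 fell among the 21356 tested, with log2 fold changes of −1.99 for Sspn (adjusted p = 0.0431), −1.66 for Igfbpl1 (0.0111), −1.24 for Fam189a2 (0.0337), −2.36 for Gal (0.0431) and 0.75 for Lgals1 (0.0388), and of 3.41 for Hmga1b (2.65e-05), 5.01 for Atp6v0c-ps2 (5.04e-05) and 4.11 for Gm9825 (5.65e-05). RLE or upper-quartile scaling gave 4 higher and 3 lower genes, without Sspn and Gal. A raw p below 0.05 was found for 1410 genes, against 1068 by chance, and DESeq2 called 250 genes, including all 9, and limma-voom called 5. Those 5 were Rbfox2, Igfbpl1 and the 3 copies. The stricter filter and the fit on only the 2 groups compared called the same 5. Sspn, Gal, Lgals1 and Fam189a2 were not called in these 3 settings. With the replicate number as a block Igfbpl1 was lost too, and only Rbfox2 and the 3 copies were called. Without control replicate 1, control replicate 2, heterozygous replicate 2, homozygous replicate 1 or homozygous replicate 2, the count was 4, 4, 20, 69 or 223.

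Among the fixed lists, genes of hypoxia and glycolysis stood out in homozygous hearts. Of 32 members, 29 had a positive fold change, with a median of 0.46 on the log2 scale, and the list moved up (camera adjusted p = 2.08e-11; adjusted p = 0.859 with an estimated correlation). No member passed over all genes, while 9 rose adjusted over the list alone. Examples are Higd1a, a mitochondrial protein induced by hypoxia (log2 fold change 0.76 ± 0.123 SE), Ankrd37 (1.10 ± 0.244), the mitophagy receptor Bnip3 (0.90 ± 0.184) and the glycolytic enzyme Tpi1 (0.45 ± 0.12). The call held without each of the 6 libraries in turn, with an adjusted p of 1.99e-06 at most.

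Genes of the outflow tract and second heart field moved down. Of 21 members 19 had a negative fold change, with a median of −0.33 (adjusted p = 0.00182; adjusted p = 0.859 with an estimated correlation). Wnt5a, a secreted ligand of non-canonical Wnt signalling, fell adjusted over the list alone (−0.45 ± 0.092 SE), as 1 of 21 members against 0 over all genes. The semaphorin gene Sema3c stood at −0.73 ± 0.196. The call was lost without control replicate 1 (0.273) or homozygous replicate 2 (0.901).

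In the pharyngeal and foregut epithelium 14 of 18 members were negative, with a median of −0.49 (adjusted p = 0.00182; adjusted p = 0.859 with an estimated correlation); 0 passed over all genes and 0 adjusted over the list alone. Nkx2-1, a transcription factor of foregut endoderm, had 70 and 25 counts in the controls and 2 and 4 counts in homozygous hearts. Without control replicate 1 the adjusted p was 0.184, and without homozygous replicate 2 the direction turned (0.901). Cell cycle genes were lower by a small step, with 31 of 38 negative and a median of −0.09 (adjusted p = 0.00466; adjusted p = 0.859 with an estimated correlation), and 0 of them passed either adjustment. Cdc20 (−0.31 ± 0.080 SE) and Ccne1 (−0.35 ± 0.098) had the smallest p. That call was lost without control replicate 1 (0.582) or homozygous replicate 2 (0.317).

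Markers of surface and lining cells were higher in homozygous hearts. Endocardium and endothelium had 19 of 23 members positive (median 0.16, adjusted p = 0.0174) and epicardium 12 of 16 (median 0.43, adjusted p = 0.0267), each with adjusted p = 0.859 with an estimated correlation. Adjusted over the list alone, Emcn (0.66 ± 0.163 SE), Sox17 (0.78 ± 0.213) and Pecam1 (0.38 ± 0.104) rose and Npr3 (−0.40 ± 0.093) fell among 23 endothelial members, and Krt19 rose (1.57 ± 0.227) among 16 epicardial members; 0 of either list passed over all genes. The endothelial call was lost without control replicate 2 (0.757) or homozygous replicate 2 (0.238), and the epicardial call without control replicate 1 (0.136) or homozygous replicate 1 (0.467). Homozygous replicate 1 is the library with Prl8a2 at 396 CPM; Krt19 stood at 223 CPM there and at 169 CPM in homozygous replicate 2.

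Immediate early genes, which respond to handling of tissue as well as to signals, were positive in 17 of 20 members, with a median of 0.28 (adjusted p = 0.000694; adjusted p = 0.859 with an estimated correlation; 0.152 without control replicate 2). Adjusted over the list alone, Ccn2, a target of YAP signalling, rose (0.87 ± 0.172 SE), as did Ier3 (2.17 ± 0.394) and Atf3 (0.57 ± 0.152), against 0 over all genes. Ier3 stood at 32.1 CPM in homozygous replicate 1, the library with Prl8a2, and at 14.2 CPM in replicate 2.

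The other 23 lists did not pass in this comparison (adjusted p of 0.0669 or more). Single members of these lists moved even so, adjusted over the list alone and with 0 over all genes. Actn2, the alpha-actinin of the sarcomeric Z-disc, fell (−1.06 ± 0.176 SE, 1 of 28 sarcomere members). Among 20 trabecular and chamber genes 3 rose and 2 fell, among them the natriuretic peptide gene Nppb (1.45 ± 0.232), Ankrd1 (0.65 ± 0.141), Sema3a (−0.45 ± 0.098) and the connexin gene Gja5 (−0.74 ± 0.169). The collagen genes Col12a1 (−0.71 ± 0.132) and Col2a1 (−0.69 ± 0.140) fell among 44 matrix genes. Itga6 (0.83 ± 0.145), Rhoc (0.44 ± 0.086), Cd36 (0.60 ± 0.132) and the p53 target Cdkn1a (0.78 ± 0.153) rose as the only such member of their lists. Among 27 cardiac transcription factors 0 passed; Nkx2-5, the locus of the Cre, stood at −0.47 ± 0.196 and Tbx3 at −0.43 ± 0.129. Of 39 splicing regulators 0 passed, with Rbfox1 at −1.20 ± 0.306 and Mbnl2 at 0.29 ± 0.081.

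**Figure D2:**
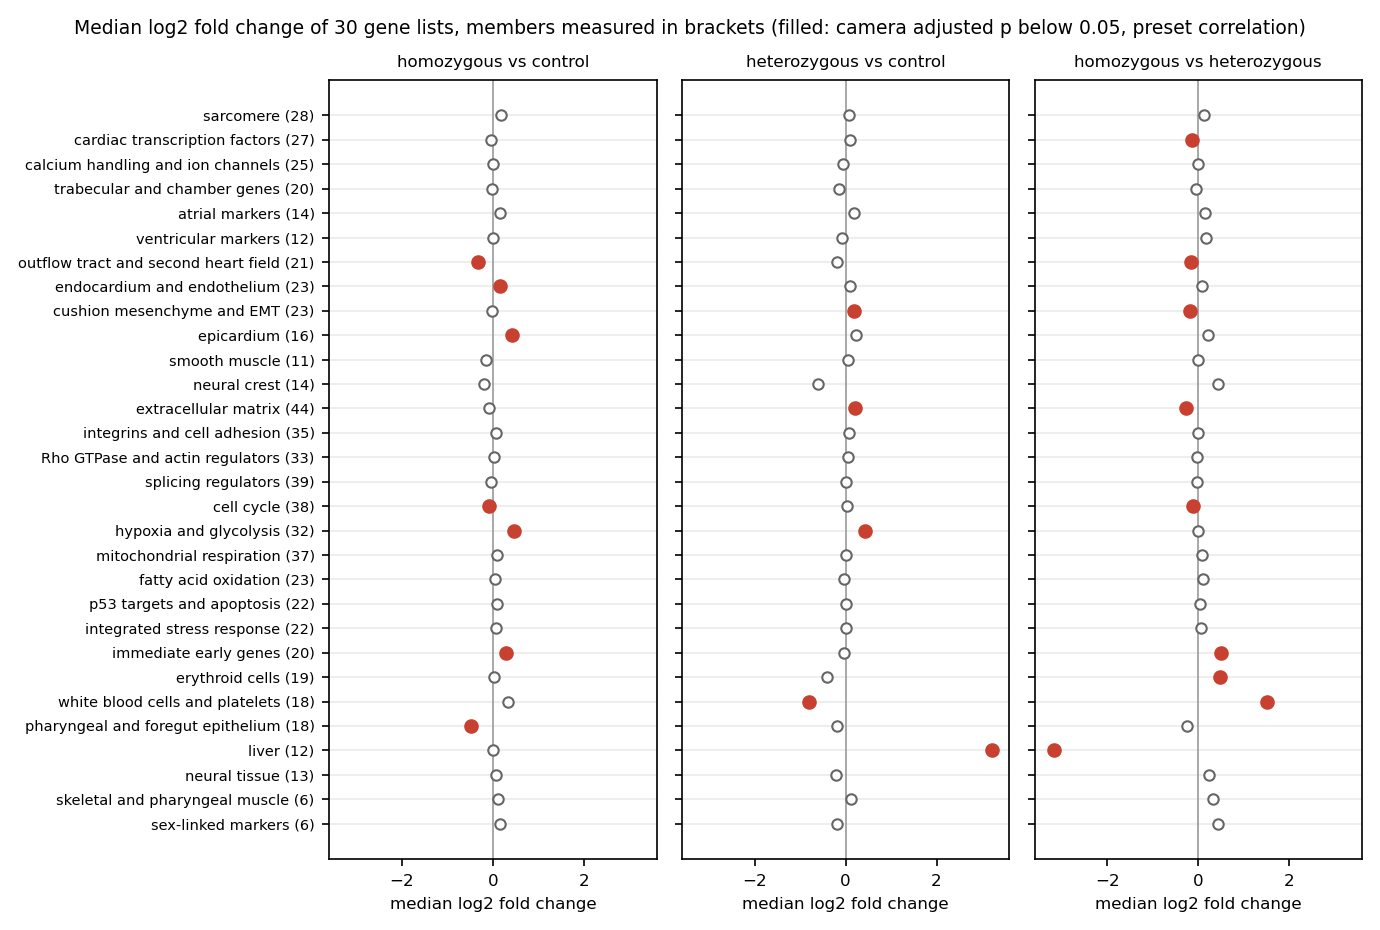
Median log2 fold change (horizontal axis) of 30 gene lists in each comparison; a point is a list, filled where its camera adjusted p with a preset correlation was below 0.05. The hypoxia list lay at 0.46 and 0.43 against control, and the liver list at 3.22 in heterozygous against control hearts.

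Heterozygous deletion was compared with control to ask what the loss of 1 allele changes. The genes that rose included several transcription factors at low levels. Foxa3 stood at 0.147 ± 0.0107 CPM in control and 3.46 ± 1.25 CPM in heterozygous hearts, Onecut3 at 0.122 ± 0.0254 and 4.31 ± 1.13 CPM, and Hhex, a transcription factor of endoderm and vessels, at 8.06 ± 0.792 and 23.9 ± 2.89 CPM. Kif12 rose from 2 and 1 counts in the controls to 136 and 310 counts, and Paqr9 rose from 4.13 ± 0.362 to 16.8 ± 1.26 CPM. These genes rose in the libraries whose 12 liver genes summed to 147 and 133.4 CPM, against 5.03 and 18.4 CPM in the controls. With only the heterozygous and control groups in the fit they were called along with Alb, Hnf4a and Serpina1a of the liver list. The same 3 gene copies as in homozygous hearts rose, Hmga1b to 75.0 ± 0.779 CPM, Gm9825 to 23.5 ± 1.80 CPM and Atp6v0c-ps2 to 19.6 ± 0.716 CPM. Fam189a2 fell to 26.9 ± 0.939 CPM and Igfbpl1 to 21.03 ± 3.36 CPM.

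In all, 9 genes rose and 2 fell among the 21356 tested. Adjusted p was 0.0177 for Onecut3, 0.0226 for Foxa3, Kif12, Paqr9 and Fam189a2, 0.0307 for Igfbpl1 and 0.0418 for Hhex. A raw p below 0.05 was found for 1589 genes, and DESeq2 called 244 genes, including all 11, and limma-voom called 3. Those 3 were the copies Hmga1b, Atp6v0c-ps2 and Gm9825, whose counts are uncertain. The stricter filter called the same 3. Onecut3, Foxa3, Kif12, Paqr9, Hhex, Fam189a2 and Igfbpl1 were called in neither setting. Without control replicate 1, control replicate 2, homozygous replicate 1 or homozygous replicate 2 the count was 4, 3, 148 or 71, and with only the 2 groups in the fit it was 39.

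Liver genes were higher in heterozygous hearts. All 12 measured members had a positive fold change, with a median of 3.22 (also with Serpina1a, at 0 counts in the controls, set to its bound), and the list moved up (adjusted p = 2.76e-10; adjusted p = 0.938 with an estimated correlation). Adjusted over the list alone 5 members rose, against 0 over all genes, among them the nuclear receptor gene Hnf4a (4.99 ± 0.730 SE), Apoa2 (1.58 ± 0.325) and the albumin gene Alb (4.69 ± 1.299). Serpina1a was at least 46.4-fold higher, by a floor of 3 counts over the control group. The 12 genes summed to 5.03 and 18.4 CPM in the controls, 147 and 133.4 CPM in heterozygous hearts, and 24.7 and 2.58 CPM in homozygous hearts. The call held without each of the 6 libraries in turn (adjusted p of 6.58e-07 at most).

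White blood cell and platelet genes moved the other way. Of 18 members 17 were negative, with a median of −0.81 (adjusted p = 1.91e-05; adjusted p = 0.938 with an estimated correlation), and 3 fell adjusted over the list alone against 0 over all genes. Lyz2, the lysozyme of macrophages, stood at −2.27 ± 0.481 (SE) and Coro1a at −1.34 ± 0.354, and Cx3cr1 had 0 counts in both heterozygous libraries against 22 in the controls, at least 8.38-fold lower. The call held without each library (0.0229 at most), and the liver genes were raised in the same 2 heterozygous libraries (147 and 133.4 CPM).

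Hypoxia and glycolysis genes were higher in heterozygous hearts too, as in homozygous hearts (median 0.46), where the liver genes summed to 24.7 and 2.58 CPM. Of 32 members 29 were positive, with a median of 0.43 (adjusted p = 5.69e-11; adjusted p = 0.938 with an estimated correlation), and 12 rose adjusted over the list alone against 0 over all genes. They include the glycolytic enzyme gene Aldoc (1.19 ± 0.292 SE), Pdk1, a kinase that inhibits pyruvate dehydrogenase (0.46 ± 0.124), Higd1a (0.44 ± 0.123) and Bnip3 (0.71 ± 0.184). The call held without each library (1.07e-05 at most), again in the libraries with the raised liver genes (147 and 133.4 CPM).

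Extracellular matrix genes were positive in 30 of 44 members, with a median of 0.20 (adjusted p = 0.00443; adjusted p = 0.969 with an estimated correlation; 0.139 without control replicate 2). Adjusted over the list alone 5 rose, against 0 over all genes, with Lama1 (1.43 ± 0.202 SE), Nid1 (0.45 ± 0.104) and Col6a2 (0.62 ± 0.151) among them. Cushion mesenchyme genes were positive in 15 of 23 members, with a median of 0.18 (adjusted p = 0.0232; adjusted p = 0.938 with an estimated correlation; 0.225 without control replicate 2). The hyaluronan synthase gene Has2 (0.58 ± 0.114) and Tgfb2 (0.49 ± 0.099) were the 2 members that rose adjusted over that list alone. Both lists were measured in the libraries with the raised liver genes.

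The other 25 lists did not pass (adjusted p of 0.117 or more), but several of their members moved adjusted over the list alone, with 0 over all genes. The cardiac transcription factor genes Gata6 (0.53 ± 0.096 SE), Gata4 (0.67 ± 0.145) and Gata5 (0.63 ± 0.151) rose, 3 of 27 members. Of 14 atrial genes 3 rose and 2 fell, with Nr2f2 (0.68 ± 0.083), Nr2f1 (0.61 ± 0.124) and Stard10 (0.51 ± 0.123) higher and the potassium channel gene Kcnj3 (−1.22 ± 0.371) lower. Of 25 ion channel and calcium handling genes 2 rose and 1 fell, with the pacemaker channel gene Hcn4 (1.04 ± 0.155) higher and Kcnj2 (−0.82 ± 0.197) lower. Itga6 rose (0.72 ± 0.145), and of 20 immediate early genes Jun rose (0.36 ± 0.085) while Ccn2 (−0.88 ± 0.173) and Ccn1 (−0.52 ± 0.111) fell. All of these were measured in the 2 libraries whose liver genes summed to 147 and 133.4 CPM, against 5.03 and 18.4 CPM in the controls.

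**Figure D3:**
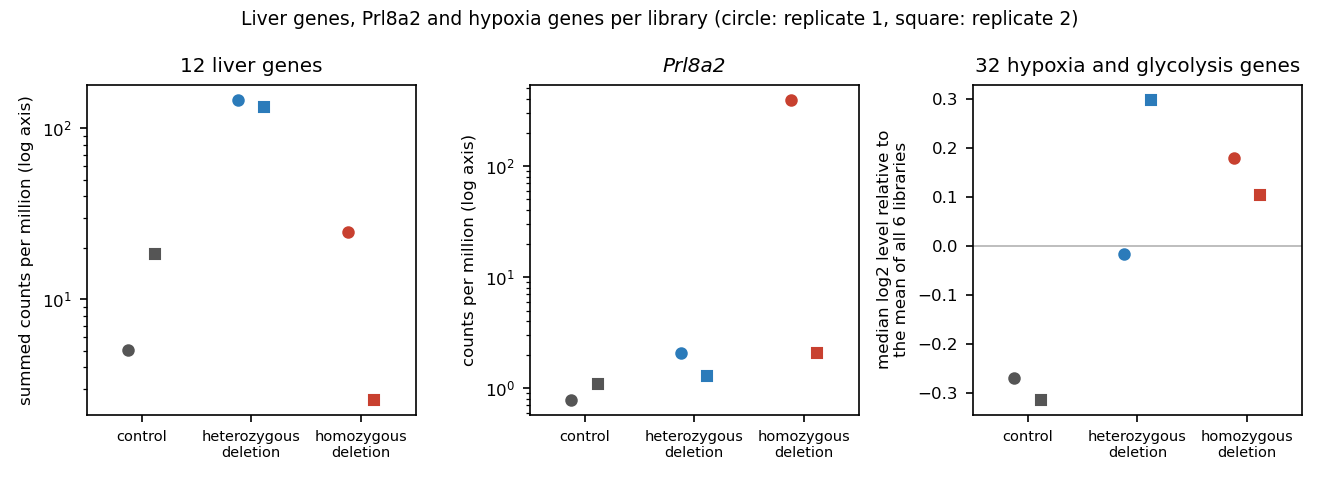
Liver genes (summed CPM of 12 genes, log axis), Prl8a2 (CPM, log axis) and hypoxia genes (median log2 level of 32 genes relative to the mean of all 6 libraries) in each library; circles are replicate 1 and squares replicate 2. The liver sum was 147 and 133.4 CPM in heterozygous hearts, Prl8a2 reached 396 CPM in homozygous replicate 1 alone, and the hypoxia median was −0.27 and −0.32 in the controls and −0.02 to 0.30 in the 4 deletion libraries.

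Homozygous hearts were compared with heterozygous hearts to ask what the loss of the remaining allele adds, which also tests whether the 2 effects against control differ. The genes with the smallest p were the relaxin receptor gene Rxfp1, at 1.75 ± 0.363 CPM in heterozygous and 12.4 ± 1.59 CPM in homozygous hearts, Ccn2 (25.003 ± 5.82 and 83.8 ± 3.46 CPM) and the endothelin gene Edn1 (8.79 ± 0.988 and 28.3 ± 2.995 CPM), all higher in homozygous hearts, and Rbfox2, Foxa3 and Paqr9, all lower. Their adjusted p ranged from 0.0517 for Rxfp1 to 0.138 for Edn1, so 0 of 21356 genes passed with edgeR. A raw p below 0.05 was found for 2214 genes, against 1068 by chance, DESeq2 called 353 genes, and limma-voom called 0. Without homozygous replicate 1 the count was 170 and without homozygous replicate 2 it was 230; it was 2, 2, 10 and 4 without control replicates 1 and 2 and heterozygous replicates 1 and 2.

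Trabecular and chamber genes did not pass as a list (9 of 20 positive, median −0.05, adjusted p = 0.764), and 0 passed over all genes. Adjusted over the list alone, Nppb (2.16 ± 0.238 SE), Ankrd1 (0.85 ± 0.141) and the neuregulin gene Nrg1 (0.90 ± 0.197) rose and Adamts1 (−0.39 ± 0.104) fell. Immediate early genes were positive in 15 of 20 members, with a median of 0.51 (adjusted p = 0.00172; adjusted p = 0.956 with an estimated correlation; 0.0579 without heterozygous replicate 2). In that list 6 rose and 1 fell adjusted over the list alone, with Ccn2 at 1.75 ± 0.176, Atf3 at 0.81 ± 0.152, Ccn1 at 0.68 ± 0.112 and Jun at −0.38 ± 0.085. The splicing regulator gene Mbnl2 rose (0.60 ± 0.082), the only one of 39 in its list, and Rbfox1 stood at −1.20 ± 0.306. Emcn rose (1.11 ± 0.164), the only one of 23 endothelial genes.

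Several lists of heart formation were lower in homozygous than in heterozygous hearts. Cardiac transcription factors had 18 of 27 members negative (median −0.14, adjusted p = 0.00681; adjusted p = 0.927 with an estimated correlation), and Gata6 (−0.59 ± 0.096 SE), Tbx3 (−0.72 ± 0.129) and Tbx2 (−0.62 ± 0.113) fell adjusted over the list alone, 3 members against 0 over all genes. The outflow tract and second heart field had 15 of 21 negative (median −0.16, adjusted p = 0.00321; adjusted p = 0.983 with an estimated correlation; 0.756 without homozygous replicate 2). Extracellular matrix had 37 of 44 negative (median −0.26, adjusted p = 5.99e-06; adjusted p = 0.671 with an estimated correlation), with Lama1 (−1.74 ± 0.204) and Col5a1 (−0.59 ± 0.121) as the 2 that fell adjusted over the list alone. Cushion mesenchyme had 21 of 23 negative (median −0.17, adjusted p = 0.00321; adjusted p = 0.671 with an estimated correlation; 0.0659 without homozygous replicate 2). Cell cycle genes had 31 of 38 negative (median −0.12, adjusted p = 0.00172; adjusted p = 0.983 with an estimated correlation), with Cdc20 at −0.33 ± 0.080 and Plk1 at −0.35 ± 0.086. Over all genes 0 members of these lists passed. The heterozygous libraries of this comparison held liver genes at 147 and 133.4 CPM, against 24.7 and 2.58 CPM in the homozygous ones. Among atrial and channel genes, whose lists did not pass, Nr2f2 (−0.58 ± 0.082), Nr2f1 (−0.65 ± 0.124), Hcn4 (−0.58 ± 0.154) and Ryr2 (−0.75 ± 0.181) fell and Kcnj2 (0.99 ± 0.197) rose adjusted over the list alone. The sarcomere gene Actn2 fell by the same test (−0.90 ± 0.176).

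Genes of other tissues separated the deletion groups. All 12 liver genes were lower in homozygous hearts, with a median of −3.17 (adjusted p = 2.95e-10; adjusted p = 0.671 with an estimated correlation), and 5 fell adjusted over the list alone against 0 over all genes, among them Apoa2 (−2.25 ± 0.335 SE), Hnf4a (−4.64 ± 0.712), Apom (−2.11 ± 0.454) and Apob (−4.03 ± 0.930). White blood cell and platelet genes were higher in 17 of 18 members, with a median of 1.5 (adjusted p = 8.75e-07; adjusted p = 0.671 with an estimated correlation), and 7 rose adjusted over the list alone against 0 over all genes, with Coro1a (1.53 ± 0.354), Fcer1g (1.84 ± 0.492) and Lyz2 (1.83 ± 0.476) as examples. Erythroid genes were higher in 18 of 19 members, with a median of 0.48 (adjusted p = 0.0313; adjusted p = 0.983 with an estimated correlation) and 0 past either adjustment; the direction turned without heterozygous replicate 2 (0.811), and the call was lost without homozygous replicate 2 (0.541). Hypoxia and glycolysis genes did not differ in one direction (16 of 32 positive, median 0.00, adjusted p = 0.936). The other 21 lists did not pass (adjusted p of 0.163 or more).

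The 3 genotypes were also compared as a series. Of the 9 genes called in homozygous against control hearts, 5 had a heterozygous mean between the other groups; the heterozygous change was 33.9% of the homozygous change on the log2 scale for Rbfox2, 29.6% for Lgals1, 39.8% for Gal, 43.3% for Sspn and 78.2% for Igfbpl1. For Hmga1b, Atp6v0c-ps2, Gm9825 and Fam189a2 it was 104.3% to 105.7%. Across genes, which are not independent replicates, the 2 sets of fold changes against control correlated at 0.358, below the mean of 0.505 (0.486 to 0.530) in 20 simulations of unchanged groups sharing the controls. Their covariance was 0.154, against a simulated 0.142 (0.131 to 0.153), and 60.1% of genes had the same sign, against 66.7%. Calls shared by both comparisons were 3 higher and 2 lower, against simulated means of 0.6 and 0.2, with highest values of 3 and 2 that equal the observed counts. With 1 control library for each comparison, a split chosen after the data were seen, the correlation was −0.0802 (homozygous against control replicate 1, simulated −0.00157 to 0.0475) and 0.0503 (homozygous against control replicate 2, simulated 0.0026 to 0.065). Shared calls in either split were 3 higher and 0 lower, against at most 2 and 2 in the simulations.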

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

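The tests of the liver pattern in this part were chosen after the result was seen.

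A direct test of homozygous against heterozygous hearts found 9 gene lists whose changes against control differed between the deletion groups, by camera with a preset correlation; 0 of them passed with an estimated correlation. The median log2 difference, homozygous minus heterozygous, was −3.165 for liver genes, −0.26 for extracellular matrix, −0.172 for cushion mesenchyme, −0.156 for the outflow tract and second heart field, −0.137 for cardiac transcription factors and −0.118 for cell cycle genes. It was 1.5 for white blood cells and platelets, 0.508 for immediate early genes and 0.481 for erythroid cells.

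Liver genes were raised in both heterozygous libraries. The rise did not grow with the number of deleted alleles in these libraries, as all 12 measured members were lower in homozygous than in heterozygous hearts. The list was flagged by that same difference, so this is not a separate test of dose. Liver bud tissue carried along with the dissected hearts cannot be told apart from a rise of these genes within heterozygous hearts. That 11 of the 12 members had both heterozygous libraries above both controls, with Apoa1 the exception and Afp at 84.5 and 64.7 CPM, follows from the rise of the list and favours neither. All members but Serpina1a also had counts in a control.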

How the results depend on the processing

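The crossed replicate block and the split of the controls were chosen after the data were seen; all other settings were planned. No named gene changed direction under any setting. For 116 pairs of a gene and a comparison, the other settings gave 1843 values. Of these 1512 kept their side of the threshold, 78 lost and 253 gained a call. Counts of called genes are given in the order homozygous against control, heterozygous against control, homozygous against heterozygous, with 9, 11 and 0 as reported. No filter gave 532, 475 and 779, and DESeq2 gave 250, 244 and 353. The stricter filter and limma-voom each gave 5 and 3 and left the third at 0, and fitting only the 2 groups compared gave 5 and 39. Leaving out each library in turn gave 4 to 223, 3 to 148 and 2 to 230. RLE scaling (7, 11, 0), upper-quartile scaling (7, 10, 0) and removal of haemoglobin and mitochondrial genes (9, 11, 0) stayed within 1.5 times. The causes were not tested.

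The fit with the replicate block gave 4, 3 and 0 genes, of which Hmga1b, Atp6v0c-ps2 and Gm9825 were called in both comparisons against control and Rbfox2 in the homozygous one, and 6, 5 and 8 lists, and a correlation of fold changes of 0.356; the epicardial list (0.0872) and the erythroid list (0.0824) lost their call under it. The labels do not state that the numbers pair libraries. Deviations from the group means correlated at 0.033, 0.135 and −0.237 between groups, which cannot show whether libraries were paired. Since the number matches sex in each group, the block also takes up sex, which the reported fit leaves out. The crossed replicate block gave 38, 49 and 117 genes.

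Rbfox2 in heterozygous against control hearts passed with no filter (log2 fold change −0.49) and with DESeq2 (−0.49). In homozygous against heterozygous hearts it passed with no filter (−0.99), DESeq2 (−0.99), the crossed replicate block (−0.98) and without either homozygous library, with a range of −1.04 to −0.95 over the left-out libraries. Lists past the test numbered 7, 5 and 9 as reported, 0 in each comparison with an estimated correlation or with fry, and 3 to 14, 3 to 12 and 7 to 15 when libraries were left out; the higher ends came without homozygous replicate 1 (14 and 15) and, for heterozygous against control, without heterozygous replicate 2 (12) and control replicate 1 (11). The correlation of the 2 sets of fold changes was 0.246 to 0.309 without a deletion library and 0.359 with RLE scaling. With the controls split so that none was shared it was −0.0802 with homozygous hearts against control replicate 1 and 0.0503 against control replicate 2, so the reported 0.358 rests on the shared controls. At this size the simulated tests recovered 23.3% of genes changed 1.5-fold in homozygous against control hearts. Those genes had a mean of at least 5 CPM and no spread of their own around the trend. Smaller changes were mostly below detection there, and the rate in the measured libraries is not known.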

Other observations

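The genes and the sterol list of the next 2 paragraphs, and every test of the gene copies and the dose tests of the hypoxia list, were chosen after values were seen; the comparison of the hypoxia list with matched lists was planned before its result.

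Sterol synthesis genes were raised in heterozygous hearts. A list of 22 genes of cholesterol metabolism was written after at least Hmgcs1, Sqle, Nsdhl, Fdft1, Msmo1, Insig1 and Srebf2 had been seen among changed genes, so it is not independent of these libraries. Of its genes 22 of 22 were higher than in control, with a median of 0.50 on the log2 scale (camera p = 2.72e-14; p = 0.113 with an estimated correlation), and 20 rose adjusted over the list alone against 0 over all genes. Hmgcs1 stood at 246 ± 21.1 CPM in control, 364 ± 68.3 CPM in heterozygous and 234 ± 33.5 CPM in homozygous hearts. All 22 were lower in homozygous than in heterozygous hearts (median −0.56), while homozygous and control hearts differed little (median −0.05, 5 of 22 positive, 0 past the list-alone adjustment). Per library the median level relative to all 6 was −0.08 and −0.22 in control, 0.16 and 0.53 in heterozygous and −0.09 and −0.28 in homozygous hearts. The 12 liver genes were raised in the same 2 heterozygous libraries, at a sum of 147 and 133.4 CPM against 5.03 and 18.4 CPM in control and 24.7 and 2.58 CPM in homozygous hearts.

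A few genes picked after their levels were seen, of which only Nkx2-1 is in a fixed list, set 1 group apart from the other libraries. Shox2, a transcription factor of the sinus node, stood at 46.1 and 32.5 CPM in heterozygous hearts against 18.3 to 30.1 CPM in the other 4 libraries, Wnt2 at 149 and 148 CPM against 69.5 to 97.1 CPM, Sfrp5 at 144 and 165 CPM against 36.9 to 77.1 CPM, and Reln at 108 and 143 CPM against 26.6 to 41.0 CPM. The surfactant gene Sftpa1 stood at 1.86 and 1.29 CPM in the controls against 0.376 to 0.479 CPM in the 4 deletion libraries, and Nkx2-1 at 1.22 and 0.351 CPM against 0 to 0.0799 CPM.

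The 5 genes called in both comparisons against control form a further pattern, led by the copies Hmga1b (chromosome 11), Atp6v0c-ps2 (6) and Gm9825 (6). A change that grows with the number of deleted alleles is argued against for these 3 copies and Fam189a2, where the upper 95% bound of the ratio of the second step (heterozygous to homozygous) to the first was at most 0.0225 and 0.16; for Igfbpl1, with a bound of 0.519, it stays open. The copies' near-identical parents Hmga1, Atp6v0c and Rnps1 all lie on chromosome 17 within 0.72, 2.67 and 2.42 Mb of Nkx2-5, the locus of the Cre, with log2 fold changes of −0.34, −0.39 and −0.46 in deletion against control hearts. Their raw p was 0.00637, 0.0317 and 0.000234 (edgeR quasi-likelihood), and none passed over all genes (adjusted p = 0.208 for Rnps1). Of the other 2 copies compared by sequence, Gm14292 was higher in deletion hearts (2.85, a gain of 1.58 CPM, adjusted p = 0.11 by the same test), and its parent Wtap lies on chromosome 17, 13.87 Mb from Nkx2-5. Gm5256 was lower (−5.86, a change of −0.301 CPM, adjusted p = 0.302). Its parent Slc25a5, at 93.5% identity, lies on the X chromosome. A strain haplotype on chromosome 17 carried with the Cre allele cannot be told apart from other causes: with the parents left out, 2 of 34 genes with like changes in both deletion groups lay within 10 Mb of Nkx2-5 against 439 of all 21351 tested (odds ratio 2.99, 95% interval 0.346 to 11.8, Fisher's exact p = 0.154, two-sided), and the controls' Cre status is not in the labels. Reads shared between parent and copy cannot be told apart from expression of the copy. Of the 3 copies, 2 had a parent with more counts than the copy gained, whereas Atp6v0c, at 13.4 CPM in control, fell short of the 17.5 CPM gained. Parent and copy summed to 354.9 CPM in control and 346.9 CPM in deletion hearts for Hmga1b. The sum fell from 182.2 to 153.7 CPM for Gm9825 and rose from 13.9 to 28.3 CPM for Atp6v0c-ps2, so the 3 copies were not alike.

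Hypoxia and glycolysis genes were higher in both deletion groups, with 24 of 32 members having all 4 deletion libraries above both controls (75% of members, against 7.16% of all genes and 6.67% by chance for a single gene). This count follows largely from the rise of the list in both comparisons, which share these controls. Its members also moved together (estimated correlation 0.414), so the count is not separate evidence. GC content and expression level are argued against as the cause, since the median lay at percentile 100 of 10000 random lists matched on both in each comparison. Growth with the number of deleted alleles cannot be told apart from a like level in both deletion groups, since the second step of the list's level was 0.578 of the first without heterozygous replicate 2 and −0.266 of it without heterozygous replicate 1. Also open is any difference of the controls from both deletion groups, in biology or in handling, and the 2 controls alone set the baseline.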
